A study of Arabidopsis thaliana with 6 samples.

How the data were processed

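Transcript levels were measured with 6 Affymetrix ATH1 microarrays in whole Arabidopsis thaliana seedlings of the double mutant egr1-1egr2-1, in which the protein phosphatase genes EGR1 and EGR2 are mutated, per the labels. The 6 arrays fell into 2 groups of 3. Seedlings 7 days old were moved either to fresh control agar at a water potential of -0.25 MPa or to agar infused with polyethylene glycol at -1.2 MPa, and were collected 96 h later, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, since the description field named the control condition for all 6 samples. Per the series' design text, the 3 arrays of a group came from separate experiments. Wild-type seedlings were not analysed here, so the only comparison was stress against control within the mutant.

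The deposited values were MAS5 signal intensities on a linear scale, per the submitters' processing notes and the values themselves. Neither a software version nor the settings of MAS5 are given in the sources used here. After trimming 2% of the probe sets at each end, the mean signal was 500 on every array, so each array had been scaled to the same trimmed mean, and a change in the total RNA of the seedlings is not visible in such values. A second deposited table of the series gave intensity values for the same 6 arrays that differed from the first at 0 positions. That table also held 6 columns of per-sample values that matched none of the sample labels, and these were not used. The tables used here carried no detection calls.

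The table held 22810 probe sets, of which 64 were array controls and were left out of all tests across genes. In the platform annotation used here 13513 probe sets named exactly 1 gene, 503 named several and 8794 had no entry. Of the single-gene probe sets, 13436 were matched by gene identifier to the gene table of the TAIR10.1 assembly, which was used only for current names, for chromosome membership and for gene order. Probe sets with several genes or with no entry were counted but not named, and for that reason many well-known stress genes could not be reported. Where several probe sets named a gene, the one with the highest mean over all arrays was used.

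Values were transformed to log2 with no pseudocount, because all were above 0. Probe sets with a mean log2 value above the 40th percentile over the 6 arrays were tested, which left 13647 probe sets and corresponded to a geometric mean signal above 114. The groups were compared with limma (lmFit and eBayes) version 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are differences of mean log2 values given as linear ratios, stress over control for rises and control over stress for falls. After the results had been seen, folds of genes whose signal in the dimmer group did not exceed the highest of 15 bacterial control probe sets on any array of that group were bounded, with the highest bacterial control of each array in place of the lower signal, and these are given as "at least"; this takes the bacterial probe sets as a measure of background. The number of arrays limits the precision, with 4 residual degrees of freedom in the fit of all 6 arrays. On simulated arrays with the means and spreads of the 13647 tested probe sets and 200 changed ones, the stress-against-control fit recovered 0% of changes of 0.5, 48% of changes of 1 and 97.5% of changes of 2 on the log2 scale, and called 0 probe sets when none had been changed. These rates hold for 200 changed probe sets. In the data 5885 passed, which makes the adjusted threshold less strict, so the rates do not apply there. IQD31, for example, passed with a log2 fold change of -0.48 (limma adjusted p = 0.015).

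Before the data were examined, 22 gene lists with 302 genes were fixed, together with the tests, the alternatives and the rule for named genes. Of these genes 52 were named by a single-gene probe set and 43 were tested. The 5 lists with at least 3 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01 against the 7240 tested genes, adjusted over the 5 lists. Camera with an estimated correlation was run beside it, as was fry, a rotation test of whether the genes of a list move on balance in 1 direction, which does not compare them with other genes. The genes named were EGR1, EGR2 and EGR3, the 12 largest rises and the 12 largest falls among probe sets past the threshold that named 1 gene and whose groups did not overlap, and up to 4 tested members of each list with the largest absolute change. P5CS1, PDH1, NCED3, HAI1, RAB18 and RD29B were also to be named, but no single-gene probe set named any of these 6 genes in the annotation used here. The EGR probe sets were fitted whether or not they passed the filter. After the annotation had been seen but before any fold change was computed, 12 further lists were written, and 30 families of genes with a shared symbol stem and at least 5 tested members were formed; both were adjusted among themselves.

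RNA quality was checked with the log2 ratio of 3-prime to 5-prime signal of the GAPDH, actin and ubiquitin control probe sets, compared by an exact permutation test. Alternatives were a replicate block, no filter, a filter at the 60th percentile, quantile normalization, centring of each array on its median, log2(value + 32), an intensity trend with a robust prior, array quality weights and leaving out each array in turn. Using the second deposited table was planned as an alternative and gave none, since its values were identical.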

Results

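The data consisted of 6 arrays of whole egr1-1egr2-1 seedlings, 3 from control agar at -0.25 MPa and 3 from agar at a low water potential of -1.2 MPa, the stress treatment. Median signals over all probe sets lay between 191 and 193 on the control arrays and between 206 and 210 on the stress arrays. Across tested probe sets, Pearson's r between arrays was 0.950 to 0.974 within the control group, 0.966 to 0.975 within the stress group and 0.769 to 0.813 between the groups; these correlations are across probe sets, which are not independent replicates. The first principal component held 80.5% of the variance. The comparison asked which transcripts differed between the stress and the control treatment in seedlings that carry mutations in both phosphatase genes.

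EGR1 and EGR2, the mutated genes, and EGR3 encode type 2C protein phosphatases of clade E. The EGR1 probe set gave a signal of 85.4 ± 13.9 (SD, n = 3) in control seedlings and 514.5 ± 58.0 (SD, n = 3) in stressed seedlings, a rise of 6.05-fold (log2 fold change 2.60 ± 0.16 SE, limma adjusted p = 2.7e-05; 2.22 on the log2(value + 32) scale). This control signal was dim: its mean lay below 98.1, the highest signal of a bacterial control probe set on any array, and the signal on a control array was at the lowest 1.13 times the highest bacterial control of the same array. The EGR2 probe set was dim in both groups, with 73.5 ± 21.5 (SD, n = 3) in control and 107.9 ± 37.1 (SD, n = 3) under stress, and lay below the filter. Its log2 fold change was 0.54 ± 0.29 (SE), with an adjusted p of 0.18. EGR3, which is not mutated in this line, rose from 313.8 ± 70.8 to 495.8 ± 83.0 (SD, n = 3 each), or 1.59-fold (adjusted p = 0.032). The EGR3 call ended with an adjusted p of 0.083 without control replicate 2, 0.099 without stress replicate 1, 0.085 without stress replicate 3 and 0.11 with no filter on dim probe sets. Where the probe sets lie relative to the mutations is not given in the sources used here, and without wild-type arrays these signals check nothing about the mutations.

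**Figure D1:**
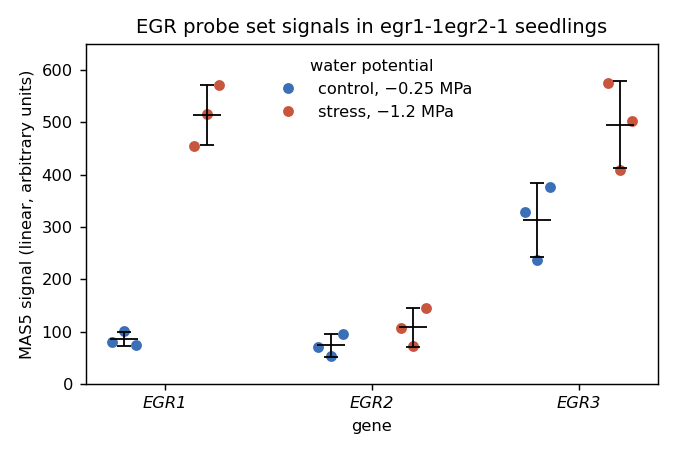
MAS5 signal (linear, arbitrary units) of the EGR1, EGR2 and EGR3 probe sets on each array, with points for the 3 control (-0.25 MPa) and 3 stress (-1.2 MPa) arrays and bars for the mean ± SD. EGR1 signals under stress (455.6 to 571.5) all lie above those of control (74.9 to 101.1), while the EGR2 signals of the groups overlap.

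A large part of the measured transcripts differed between the treatments. Of 13647 tested probe sets, 5885 (43.1%) passed the threshold, 3191 of them higher and 2694 lower under stress. A change of at least 2-fold (1 on the log2 scale) as well was seen for 1124 probe sets that were higher and 1237 that were lower. Over all 13647 tested probe sets, called or not, the 3 stress arrays lay on 1 side of the 3 control arrays for 7529 (55.2%), where chance gives 10%. Over the 7240 tested genes that a single-gene probe set named, 1668 were higher and 1317 lower. The largest changes were only partly named: of the 100 largest rises, 48 probe sets named exactly 1 gene and 51 had no entry in the annotation, and of the 100 largest falls, 51 named 1 gene and 48 had no entry.

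Among the 12 largest rises of named genes that passed the filter were ABR, an abscisic acid responsive gene of the LEA (late embryogenesis abundant) type, DFR, UGT75C1 and UF3GT of anthocyanin synthesis, SAG29, a senescence-associated sugar transporter of the SWEET family, and THI2.1, a thionin used as a marker of jasmonate response. A gene with hardly any control signal can fall below a filter on the mean over all arrays and is then not ranked. AT5G50360, for example, had 4.87 ± 1.86 in control and 983.3 ± 163.0 under stress (SD, n = 3 each). With no filter its measured log2 fold change was 7.73 (limma adjusted p = 0.0010). This control signal lay far below the highest bacterial controls of the control arrays, 52.1 to 70.9. The measured value therefore overstates what can be said of the size of this rise. SAG29 went from a signal of 43.7 ± 6.99 to 4490 ± 864 and THI2.1 from 32.4 ± 14.2 to 2943 ± 834 (SD, n = 3 each). With the bacterial controls taken as background, these are rises of at least 70.8-fold and at least 45.7-fold. On the log2(value + 32) scale the rise of SAG29 was below its bound, at 59.1-fold. The other rises were those of LEA4-5, LEA18 and AT3G17520, with log2 fold changes of at least 6.09, 3.76 and 5.91 on the same assumption, and of AT2G37870, AT2G21820 and AT4G33550, with log2 fold changes from 5.78 to 6.65. AT2G21820 did not exceed the highest bacterial control on 2 control arrays. On the log2(value + 32) scale LEA4-5 rose by 5.66 and AT2G21820 by 5.42. In 11 of the 12 the mean control signal lay below 98.1, the highest signal of 15 control probe sets for bacterial transcripts, and in 9 no control array exceeded its own highest bacterial control, so that only a lower bound of the fold can be given. For these genes the fold change depends on how a dim signal was estimated: on the log2(value + 32) scale the rise of ABR was 6.78 instead of the measured 8.28, that of AT3G17520 5.95 instead of the measured 7.18, that of SAG29 5.89 and that of THI2.1 5.51. Without control replicate 2 the measured value of AT3G17520 was 6.53, and without control replicate 3 it was 7.79.

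The 12 largest falls included EXO, a growth-promoting extracellular protein responsive to brassinosteroid, and TBL45, a member of the TRICHOME BIREFRINGENCE-LIKE family of wall acetylation proteins. EXO fell from 8878 ± 4823 to 545.4 ± 196.8 (SD, n = 3 each; log2 fold change -3.92 ± 0.43 SE) and TBL45 from 1784 ± 301 to 96.8 ± 11.2 (log2 fold change -4.20 ± 0.17 SE). AT3G05730 fell from 5742 ± 1539 to 96.7 ± 70.9 and AT2G10940 from 10720 ± 402 to 530.8 ± 275.8. The other 8 were AT3G16670, AT5G62360, AT1G22690, AT2G41090, AT3G04210, AT1G33811, AT1G06830 and AT1G66940. In 8 of the 12 the mean stress signal lay below 98.1, and in 4 no stress array exceeded its own highest bacterial control: AT3G16670 (a fall of at least 26.4-fold), AT5G62360 (at least 18.7-fold), AT3G04210 (at least 9.01-fold) and AT1G06830 (at least 8.62-fold). AT1G22690, AT2G41090, AT1G33811 and AT1G66940 had log2 fold changes from -5.52 to -4.31. AT1G22690 and AT1G33811 did not exceed the highest bacterial control on 2 stress arrays. With that control in place of the lower signals, their falls were at least 5.43 and 3.91 on the log2 scale. Both were smaller than these bounds on the log2(value + 32) scale, with log2 fold changes of -4.96 and -3.85. On the log2(value + 32) scale the falls of AT3G16670 and AT5G62360 were -5.04 and -4.70 instead of the measured -6.44 and -6.20. Without stress replicate 1 the measured values of AT3G16670 and AT3G05730 were -5.79 and -5.53. All 24 genes had an adjusted p of at most 0.0022.

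**Figure D2:**
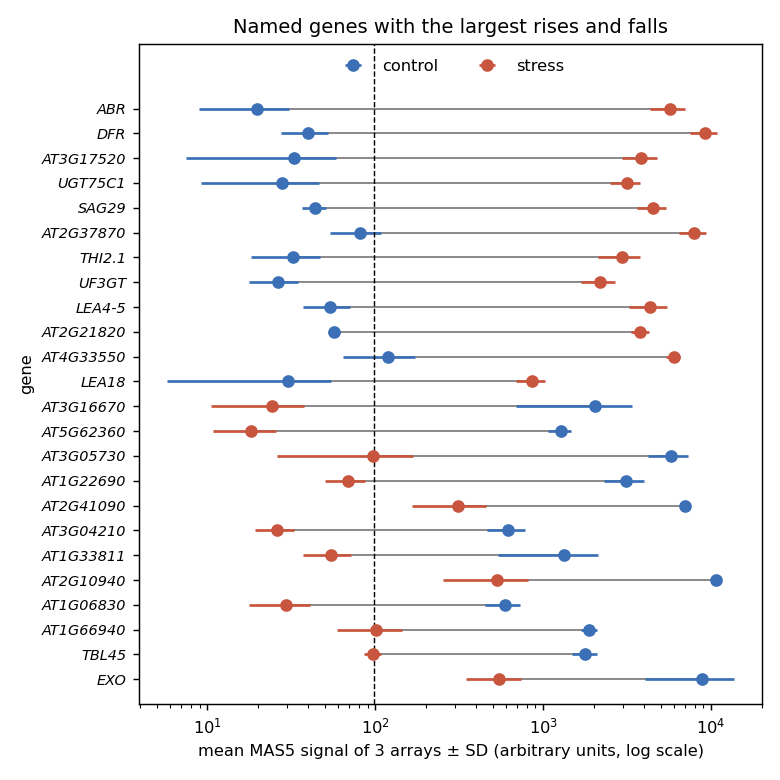
Mean MAS5 signal ± SD of the 3 control and the 3 stress arrays (arbitrary units, log axis) for the 12 named genes with the largest rises and the 12 with the largest falls, among those that passed the filter. The dashed line marks 98.1, the highest signal of a bacterial control probe set on any array, and 11 of the rises start below it.

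Dehydration and LEA genes, whose hydrophilic protective proteins accumulate in dry seeds and drying tissue, rose as a list (median log2 fold change 5.30, camera adjusted p = 0.00091; adjusted p = 0.13 with an estimated correlation). Of 20 listed genes 7 were tested, and 5 rose, 0 fell and 2 did not pass; adjusted over the list alone, 5 rose and 1, COR15B, fell. ABR rose from 19.9 ± 11.0 to 5685 ± 1340, LEA4-5 rose from 53.8 ± 16.7 to 4350 ± 1105, LEA18 rose from 30.3 ± 24.6 to 860.5 ± 170.0 and COR15A, a chloroplast stromal cold-regulated protein, rose 39.5-fold from 209.7 ± 73.7 to 8256 ± 2788 (SD, n = 3 each). The control signals of ABR, LEA4-5 and LEA18 did not exceed the bacterial controls on any control array, whose highest signals were 52.1 to 70.9. With those controls taken as background, the rises were at least 89.3-fold, 67.9-fold and 13.6-fold. On the log2(value + 32) scale the rise of LEA4-5 was below its bound, at 50.6-fold. COR15B, a close relative of COR15A, had a signal of 702.4 ± 174.1 in control and 415.2 ± 182.8 under stress (adjusted p = 0.075). The list median was 3.91 on the log2(value + 32) scale, 4.28 without control replicate 2 and 4.40 with the filter at the 60th percentile. The value of LEA18 was 3.91 on the log2(value + 32) scale, 4.28 without control replicate 2, 6.36 without control replicate 3 and 4.89 with array quality weights.

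All 3 tested flavonoid genes, of 12 listed, rose, also adjusted over the list alone, and all 3 belong to anthocyanin synthesis. DFR, dihydroflavonol reductase, rose from 39.9 ± 12.6 to 9197 ± 1705, UGT75C1, an anthocyanin glucosyltransferase, rose from 27.8 ± 18.6 to 3142 ± 653, and UF3GT, an anthocyanin glycosyltransferase, rose from 26.3 ± 8.66 to 2185 ± 501 (SD, n = 3 each). None of these control signals exceeded the bacterial controls on any control array. With those controls taken as background, the rises were at least 145-fold for DFR, 49.5-fold for UGT75C1 and 34.3-fold for UF3GT. On the log2(value + 32) scale the rise of DFR was below its bound, at 128-fold. The list had a median log2 fold change of 7.05 (camera adjusted p = 0.00027; adjusted p = 0.13 with an estimated correlation), which rests on the same control signals and was 5.76 on the log2(value + 32) scale.

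Genes of wall loosening, the expansins and xyloglucan endotransglucosylase/hydrolases, went both ways. Of 24 listed genes 7 were tested; 5 rose, 1 fell and 1 did not pass, with the same numbers adjusted over the list alone. EXPA9 rose by 1.85 on the log2 scale from 255.7 ± 50.3 to 907.6 ± 9.15, XTH19 rose 3.23-fold and EXPA4 rose 1.98-fold, whereas EXPA8 fell 3.56-fold from 1068 ± 533 to 276.9 ± 23.5 (SD, n = 3 each). The list's median was 0.69 (camera adjusted p = 0.041). This call ended with an adjusted p of 0.18 with an estimated correlation, 0.071 without control replicate 1, 0.053 without stress replicate 2, 0.070 with array quality weights and 0.073 with no filter on dim probe sets.

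Of 20 listed genes of tubulins, the subunits of microtubules, and of microtubule-associated proteins, 8 were tested; 5, all of them tubulins, fell, 0 rose and 3 did not pass, and 6 fell when adjusted over the list alone. TUB5 fell 2.95-fold from 2979 ± 538 to 1006 ± 149, TUB7 fell 1.87-fold, TUB6 fell 1.51-fold and TUA1 fell 1.48-fold (adjusted p from 0.00040 to 0.0096). TUB9 and TUB1 had log2 fold changes of -0.41 (adjusted p = 0.069) and -0.10 (adjusted p = 0.63). SPR1, a microtubule-localised protein, had 2305 ± 69.4 in control and 2636 ± 446 under stress (SD, n = 3 each; adjusted p = 0.38). The median of the list was -0.55 (camera adjusted p = 0.0044). With an estimated correlation the adjusted p was 0.18.

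Of 37 listed nuclear genes of photosynthesis 7 were tested; 6 fell, 0 rose and 1 did not pass, and all 7 fell when adjusted over the list alone. PSAN, a photosystem I subunit, fell 3.00-fold from 14039 ± 1170 to 4703 ± 733, and PRK, the phosphoribulokinase of the Calvin cycle, fell 2.94-fold from 14715 ± 2689 to 5031 ± 1054 (SD, n = 3 each). PSBW, a photosystem II subunit, fell 1.85-fold and RCA, Rubisco activase, fell 1.75-fold. The root hair markers EXPA7 and EXPA18, fixed as a sign of organ makeup, moved the other way on the same arrays. Their log2 fold changes were 2.58 and 1.68 from dim control signals (2.02 and 1.35 on the log2(value + 32) scale). EXPA7 did not exceed the highest bacterial control on 2 control arrays and EXPA18 on 1. These 2 genes do not settle whether the share of organs differed between the groups. The list's median was -0.81 (camera adjusted p = 0.00027), and with an estimated correlation the adjusted p was 0.13.

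**Figure D3:**
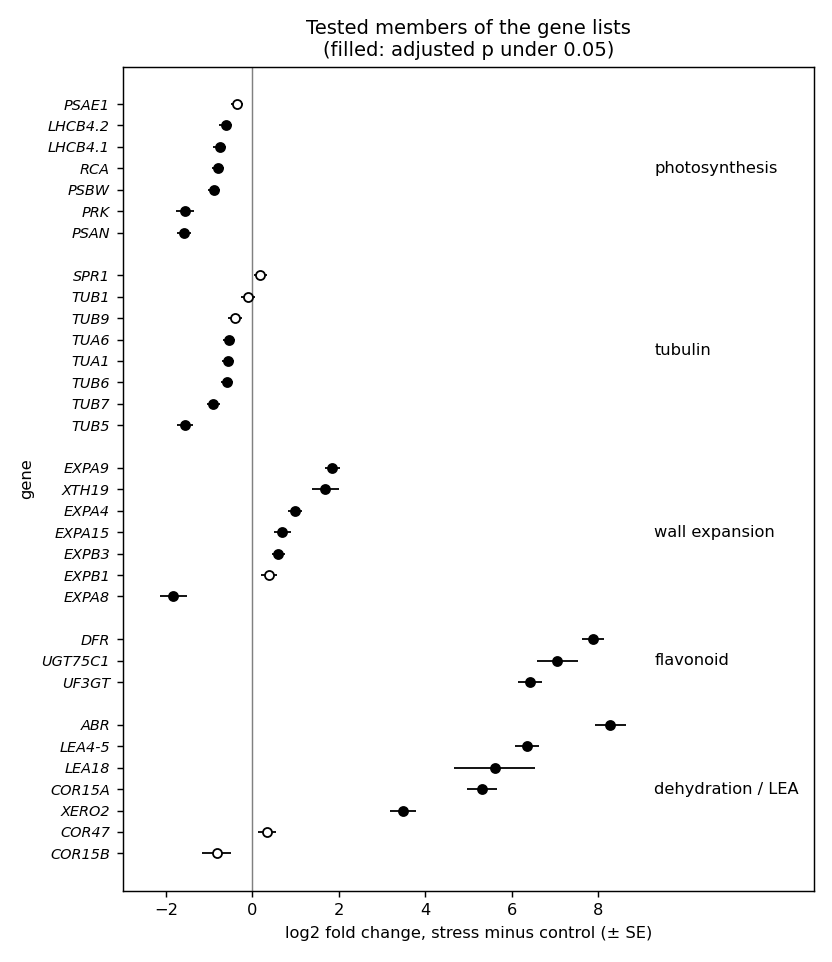
Log2 fold change, stress minus control, with SE, of every tested member of the 5 lists that could be tested, drawn as filled points where the adjusted p was under 0.05. Points are drawn at measured values. The highest, those of ABR and DFR, rest on control signals not above the bacterial controls. With those controls taken as background they stand for rises of at least 6.48 and 7.18, and on the log2(value + 32) scale for 6.78 and 7.00. The tubulin and photosynthesis genes that changed lie between -1.59 and -0.54, and the wall genes lie on both sides of 0.

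The remaining lists had fewer than 3 tested members, so only their genes are given. OAT, the ornithine aminotransferase of the proline list, rose 1.90-fold from 447.0 ± 44.4 to 848.7 ± 68.7 (SD, n = 3 each; adjusted p = 0.0014). The root hair markers EXPA7 and EXPA18, included as a sign of organ makeup, rose 5.99-fold (log2 fold change 2.58 ± 0.43 SE) and 3.21-fold (1.68 ± 0.36 SE), from mean control signals below 98.1; on the log2(value + 32) scale the values were 2.02 and 1.35. AUR1, an Aurora kinase of dividing cells, fell from 398.1 ± 14.7 to 267.1 ± 40.6 (adjusted p = 0.016), and its relative AUR2 had 208.1 ± 11.4 and 185.5 ± 30.1 (adjusted p = 0.39). BCAT4, of methionine-derived glucosinolate synthesis, fell 1.67-fold from 4625 ± 891 to 2765 ± 528 (adjusted p = 0.020). The AUR1 call ended without control replicate 3 (adjusted p = 0.055), and the BCAT4 call without control replicate 1 (0.051), control replicate 3 (0.061) or stress replicate 1 (0.061); both also ended with no filter on dim probe sets, at 0.058 and 0.078. The auxin response genes GH3.5 and GH3.3 had log2 fold changes of -0.37 (adjusted p = 0.13) and -0.33 (adjusted p = 0.51); GH3.5 passed only with array quality weights, at 0.048. IAA29, below the filter, had 273.6 ± 311.0 in control and 25.1 ± 6.88 under stress (SD, n = 3 each), and with no filter its adjusted p was 0.063. Of the jasmonate list, THI2.1 rose as given above, and PDF1.2, a plant defensin below the filter, had 91.3 ± 51.1 and 53.7 ± 16.1 (adjusted p = 0.42 with no filter). PDH2, a proline dehydrogenase below the filter, had 105.7 ± 22.1 and 71.6 ± 13.9 (adjusted p = 0.15 with no filter). HSP22, the only heat shock gene named, was below the filter, with 33.1 ± 24.3 in control and 516.6 ± 125.4 under stress, and with no filter its adjusted p was 0.022. Single-gene probe sets named 0 genes of the lists of abscisic acid metabolism, abscisic acid receptors, clade A phosphatases, raffinose and starch, aquaporins, dark-induced senescence, seed maturation and the root endodermis, and the only wax and lipid transfer gene named, WSD1, was below the filter at 11.3 ± 10.3 and 10.8 ± 10.2 (SD, n = 3 each).

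In RNA quality the groups differed by less than the SD of either group for the GAPDH and actin controls. For ubiquitin the difference, -0.087, was just above the control SD of 0.086 in size and below the stress SD of 0.16. The log2 ratio of 3-prime to 5-prime signal was 0.03 ± 0.05 in control and 0.05 ± 0.07 under stress for GAPDH, 1.15 ± 0.27 and 1.28 ± 0.39 for actin, and 0.15 ± 0.09 and 0.06 ± 0.16 for ubiquitin (SD, n = 3 each). The exact two-sided permutation p was 0.90, 0.80 and 0.40, where 3 arrays against 3 cannot go below 0.10.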

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

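No called result changed direction under the alternatives that were run. The number of probe sets past the threshold was 5885 and ranged from 4403 with the filter at the 60th percentile to 6703 with array quality weights; leaving out each array in turn gave 4606 to 5493. Of these counts only the rises of at least 2-fold moved by over 1.5 times, to 662 with the stricter filter, which tested 9098 probe sets. With each array centred on its median, 2821 were higher and 2905 lower. Replicate numbers were shared by the groups, and the fit with a replicate block called 5702 probe sets; deviations from the group means correlated at 0.0044, 0.067 and 0.27 between arrays with the same number, and both arrays matched their own number best for 1 of 3 numbers, so the numbers were not taken as pairs. With the block, EGR2 (log2 fold change 0.54) passed at an adjusted p of 0.023; over its alternatives that value ranged from 0.023 to 0.47. The block changed no other call of a targeted gene, named gene or fixed list; 32 of 64 plastid genes fell with it, against 15. EGR3 no longer passed with no filter (0.67), and leaving out arrays gave 0.48 to 0.82; its adjusted p ranged from 0.016 to 0.11. Fry, which compares a list with no other genes, gave unadjusted p of 0.00011 for dehydration and LEA genes and 5.1e-05 for flavonoid genes. For wall, tubulin and photosynthesis genes its p was 0.0018, 0.0018 and 0.00047. With an estimated correlation camera's calls ended for all 5 fixed lists, whose medians, 5.30, 7.05, 0.69, -0.55 and -0.81, do not depend on it. The wall list also ended with array quality weights (0.58) and no filter (0.65), and ranged from 0.52 to 0.83 over left-out arrays, with adjusted p from 0.021 to 0.071. The cause was not tested. With no detection calls, folds from signals near the bacterial controls are the least certain.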

Other observations

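The lists written after the annotation had been seen gave a wider view of the same response; they were tested in the same way and adjusted over the 10 of 12 that had enough tested members, and the genes named from them were chosen after their values were seen. Of 13 tested members of the LEA family 11 rose and 0 fell (median log2 fold change 3.38, or 2.00 with no filter and 2.02 with the filter at the 60th percentile; camera adjusted p = 8.3e-06; adjusted p = 0.31 with an estimated correlation). Of 51 listed genes of this family 35 were named by a single-gene probe set, and those not tested lay below the filter. A gene with hardly any control signal passes a filter on the mean only by rising, so 11 of 13 is not the share of the family. The 13 include all 7 tested genes of the fixed dehydration list. Besides the genes of the fixed list, DI21 rose 10.4-fold from 1062 ± 164 to 11014 ± 1580 and AT2G46140 rose 4.04-fold from 255.2 ± 81.1 to 1004 ± 202 (SD, n = 3 each). Of 5 tested genes used as markers of abscisic acid or drought response, 4 rose (camera adjusted p = 0.00081, and 0.31 with an estimated correlation). Among them were the ubiquitin ligase PUB19 and AT1G16850, from control signals of 38.5 ± 23.5 and 53.1 ± 12.2 to 1166 ± 166 and 2514 ± 526 (SD, n = 3 each). With the bacterial controls taken as background PUB19 rose at least 18.5-fold. On the log2(value + 32) scale PUB19 had 4.14, below its bound of 4.21 on the log2 scale, and AT1G16850 had 4.89. DI19 had 14021 ± 1723 and 14127 ± 804 (limma adjusted p = 0.94). AT5G66780, AT5G50360 and AT4G33905 of the list lay below the filter, and with no filter they rose (limma adjusted p = 0.0079, 0.0010 and 0.049). All 5 tested genes of the list of further photosystem subunits, Calvin cycle and photorespiration fell (median -1.56, camera adjusted p = 0.00024; adjusted p = 0.32 with an estimated correlation), including SBPASE, sedoheptulose bisphosphatase (2.94-fold), HPR, hydroxypyruvate reductase (2.01-fold), and the photosystem II subunit PSBY (3.19-fold). The root hair markers EXPA7 and EXPA18 had log2 fold changes of 2.58 and 1.68 on the same arrays (2.02 and 1.35 on the log2(value + 32) scale). Further flavonoid genes rose for 3 of 4 tested (camera adjusted p = 0.013, and 0.32 with an estimated correlation), with UGT78D2 at 6.11-fold and CHIL at 5.46-fold. AT5MAT of the same list lay below the filter, with 16.3 ± 9.36 in control and 801.7 ± 133.0 under stress (SD, n = 3 each). With no filter its limma adjusted p was 0.0041.

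Root hair genes and extensins, a list on organ makeup, rose for 5 of 8 tested (median 1.84, camera adjusted p = 0.013; adjusted p = 0.60 with an estimated correlation). The cellulase GH9C1 rose from 75.0 ± 54.2 to 394.3 ± 88.2 (2.11 on the log2(value + 32) scale) and the extensin HRGP1 rose 2.90-fold. The HRGP1 probe set is of a kind marked as able to bind several transcripts, so its rise may not be that of this gene alone. Class III peroxidases, secreted enzymes of the cell wall, went both ways, with 11 of 28 tested higher and 3 lower (camera adjusted p = 0.096; 0.0095 without control replicate 2, and 0.0095 to 0.62 over the alternatives). Of 9 amino acid catabolism genes 2 rose, MGL, methionine gamma-lyase (8.78-fold), and AT4G33150 (6.71-fold), 2 fell, MCCA (2.69-fold) and ETFQO (1.68-fold), and 5 did not pass (camera adjusted p = 0.78 for the list, and 0.66 to 0.94 over the alternatives of camera). The other lists tested did not pass with camera: clade E phosphatases with 3 of 5 higher and 1 lower (adjusted p = 0.46), core histones with 1 of 6 lower (0.40) and further glucosinolate genes with 0 of 3 past the threshold (0.18, with log2 fold changes from -0.54 to -0.36). EGR1 and EGR3, reported above, were among the higher clade E genes. The clade E median was 0.67, but -0.42 with the filter at the 60th percentile. The separate test with fry asks whether the genes of a list move on balance in 1 direction and compares them with no other genes; its call differed from that of camera for root hair genes and extensins (adjusted p = 0.070), amino acid catabolism (0.0076) and clade E phosphatases (0.0023). The lists of hybrid proline-rich proteins and of further jasmonate genes had too few tested members; AT2G45180 of the former fell 5.53-fold from 18803 ± 1003 to 3475 ± 922, and AT5G05600 of the latter rose 3.48-fold. None of 30 families with a shared symbol stem passed, the smallest adjusted p being 0.16, for tubulins, UDP-glycosyltransferases and SCPL carboxypeptidase-like proteins.

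The tests on EGR1 and those on differences in plastid signal between arrays of a group, in the paragraphs that follow, were chosen only after the result was seen. On the count of changed probe sets, 3 explanations were tested. The mean size of the group difference in the 3-prime to 5-prime log2 ratios of GAPDH and actin was 0.070, under the limit of 0.5 set before the result was seen, which argues against a difference in RNA quality of the kind these probe sets measure. After quantile normalization 93.3% of the called probe sets were called in the same direction. The arrays had already been scaled to the same trimmed mean, so this step could change the values only in the shape of their distributions. A change in total RNA is hidden by both kinds of scaling, so the agreement does not decide whether scaling contributed to the count. The 6 arrays can be split into 3 and 3 in only 10 ways, too few for a share under 0.05. The real split gave 5885 probe sets and the highest of the other splits 0, and 1 of the 10 splits gave as many as the real one. Every other split mixes control and stress arrays on each side, so that the group difference adds to the residual spread. Few calls were therefore to be seen there in any case, and these counts decide nothing about chance. The difference in water potential that the design names stays open beside anything else that differed between the treatments.

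The EGR1 probe set rose 6.05-fold in a line that carries a mutation in EGR1. Its log2 fold change exceeded that of AT1G79630, the largest among the other 4 tested clade E phosphatases, by 1.81 ± 0.25 (SE), which argues against cross-hybridisation with these transcripts; clade E members that were not tested are not covered. On each stress array the EGR1 signal was at least 5.83 times the highest of the 15 bacterial control probe sets, which argues against noise near the background as the source of the stress signal; the control signal was close to those controls. A candidate explanation, not tested here, is that part of the EGR1 transcript is still made in the mutant and responds to low water potential; whether the probes lie before or behind the mutation is not given in the sources used here.

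Plastid-encoded genes, outside the fixed lists, had a median log2 fold change of -0.60 over 64 tested genes, of which 15 fell and 0 rose; a joint shift had been set down as a hypothesis before the result was seen, and the camera test passed (p = 3.3e-07), but not with an estimated correlation (p = 0.21). On the same arrays the root hair markers EXPA7 and EXPA18 had log2 fold changes of 2.58 and 1.68 (2.02 and 1.35 on the log2(value + 32) scale). The median plastid signal also differed between arrays of a group, over a range of 0.63 in control and 0.75 under stress on the log2 scale, while the difference between stress and control arrays with the same replicate number was -0.47, -0.55 and -0.59. With no filter on dim probe sets 4 of the 64 fell; without control replicate 1 the count was 8 and without stress replicate 1 it was 23. Only 1 of the 6 ways to pair the arrays gave differences with so small a spread (SD 0.063; the other 5 gave 0.34 to 0.69), but 6 pairings are too few to exclude that this arose by chance. For replicates 1, 2 and 3 the plastid median was 12.21, 11.90 and 11.59 in control and 11.75, 11.35 and 11.00 under stress. The nuclear photosynthesis median was 14.08, 13.80 and 14.02 in control and 13.28, 13.51 and 13.12 under stress, in another order. Its within-group ranges were at most 0.51 of those of the plastid median. A ratio of ranges does not show whether the medians move together. It does not decide whether the share of green tissue, a shared day of growth or the priming of plastid RNA may be the source.

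Across 2133 pairs of adjacent tested genes, log2 fold changes of neighbours correlated at 0.056 (0.057 without probe sets marked as able to bind several transcripts), a weak relation. It did not exceed the highest of 1000 shuffled orders, 0.070 (0.058), the limit set before the result was seen, although only 7 (1) of the shuffled orders reached it, so chance placement was not excluded by that limit. The control probe set for 25S ribosomal RNA gave 1350 on the array of control replicate 1 and 6272 to 10130 on the other 5 arrays; without that array 5493 probe sets passed.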
